A study of Rattus norvegicus with 16 samples.

How the data were processed

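Total RNA from liver grafts and plasma of 8 rats was hybridised by the authors to 16 Agilent rat miRNA arrays in 1 colour (Cy3), 1 array per sample. Per the labels, plasma was spun at 820 g and then at 16000 g before RNA was extracted with a mirVana PARIS kit, and graft RNA was extracted with a mirVana kit. Per the file headers, the scans were read with Agilent Feature Extraction 10.7.3.1. The deposited array files give, per the file headers, background-subtracted fluorescence intensity for each spot, as a processed signal and as a total gene signal per miRNA, with marks for outlying spots and for spots well above background. The deposited series value table holds log2 values for the same 350 miRNAs, which the values themselves show: its column medians lie between 1.04 and 1.06 for graft and between 0.565 and 0.595 for plasma. Within each tissue its columns share nearly the same set of values, and it ranks the miRNAs of an array like the total gene signals (Spearman correlation from 0.990 to 1). How the table was made beyond that is not given in the sources used here, and it served as an alternative only.

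The processed signal of each of 938 miRNA probes was averaged over its 5 to 20 spots, leaving out control spots and spots marked as outliers. Each array was divided by the 75th percentile of its signal over the probes detected on every array of the fit and multiplied by the mean of these percentiles. That set held 212 probes of 116 miRNAs for the graft, 77 probes of 50 miRNAs for plasma and 44 miRNAs for all 16 arrays. Values were raised to a floor of 2 and log2 transformed, and each miRNA was represented by its brightest probe. A probe counted as detected on an array when more than 50% of its spots were well above background by the scanner software's mark, and a miRNA when any of its probes was. A miRNA was tested when its brightest probe was detected on at least 4 of 8 arrays, in each tissue for the fits of both tissues, which left 151 of 152 detected miRNAs in the graft, 128 of 130 in plasma and 108 of 111 in both. Depth of an array is its signal over background, given in the results as the 75th percentile of the probe signal and the number of miRNAs detected. No replicate arrays of 1 sample exist, so array error was not separated from differences between animals.

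Groups followed the sample titles, with 4 arrays in each of the 4 groups. Because the titles of animals 33 and 40 name opposite groups for graft and plasma, fits without both animals and with the labels exchanged in plasma or in graft were fixed as alternatives before the data were examined, as were the comparisons, the tests, the lists and the rule for named miRNAs. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided), and p values were adjusted by Benjamini-Hochberg over the miRNAs tested, with a threshold of 0.05. Graft and plasma were fitted separately with group as the only term. The difference between the tissues' effects and the mean difference between graft and plasma came from 1 fit of 4 group means over all 16 arrays. For a miRNA that its lower group detected on no array or on 1 array, that group's undetected values were raised. They were set to the lowest signal that counted as detected on their array. The result was given as at least N-fold where every array of the higher group detected the miRNA, and otherwise as no bound. Numbers of detected miRNAs and spike-in signals were compared by exact permutation tests.

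The 16 lists were hepatocyte, leukocyte, inflammation-induced, miR-17-92 and paralogs, red blood cell, platelet, mesenchymal, miR-29, epithelial, muscle, neuronal, let-7, miR-30, miR-34, Dlk1-Dio3 and miR-181. They were drawn up from general knowledge and name miRNAs enriched in a cell type or belonging to a family, not the cells present. Lists with at least 3 tested members were tested with camera from limma at a preset correlation of 0.01 between miRNAs and again with the correlation estimated from the data, adjusted over the lists of a tissue. Members past the threshold were counted over all miRNAs and adjusted over the list alone. Named miRNAs were the 10 largest increases and 10 largest decreases past the threshold in each tissue, or the 10 with the smallest p where fewer passed. For the difference between tissues they were the 10 with the smallest p, for graft against plasma the 5 at each end, with 14 miRNAs fixed for every comparison and up to 4 examples per list. In plasma the rule was applied to the titles and to the 6 undisputed animals. List members and shared miRNAs named beyond it were chosen after their values were seen. miR-155 has no probe on the array, and miR-194 was not tested in plasma. The graft files name miR-17 what the plasma files name miR-17-5p, and both were read as the same miRNA.

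The limma fit was tested on simulated log2 values in which 30 miRNAs were changed in 20 runs around the spread of the real arrays. Values were drawn independently for each miRNA, so scaling, floor, detection filter, probe choice and correlation between miRNAs were not tested. With 4 arrays per group it recovered 81% of 2-fold and 99% of 4-fold changes in the graft, and 14.5% and 57% in plasma. With 3 per group it recovered 75% and 96% in the graft and 22% and 70% in plasma. The spread came from the title groups with 4 arrays, contradictory plasma titles included, and from the undisputed animals with 3. The shares with 4 and with 3 arrays therefore do not compare the number of arrays alone. False calls made up from 4.83% to 6.42% of calls. As a further check, called miRNAs with at least 2 detected probes were read from each probe, and 0 of 72 in the graft and 0 of 24 in the undisputed plasma had probes of opposite sign. In plasma the probes of 2 miRNAs, miR-139-3p and miR-874, differed by more than 1 log2 unit.

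Alternatives were other scalings (percentile over all miRNA probes, quantile normalization, median of detected probes, none), the total gene signals, the deposited value table, the mean over probes, other detection filters, a floor of 1, a trend in eBayes, a fold threshold of 2, a spread shared over all arrays, leaving out each array in turn, and replicate or animal as a block. Chosen after the data had been seen were normexp background correction of the median signals (offset 50), slide row as a block, combinations of the label settings with other scalings or with 1 array left out, raising undetected values to the lowest detected signal of their array, and the graft fit without the 1 graft array that the scanner software marked for evaluation. The same mark on 6 of the 8 plasma arrays left too few arrays for such a fit in plasma. Genomic positions were not used here, since the file headers name another genome build than the annotation at hand, which served only to check names (346 of 350 miRNAs found). Control probes whose targets the files do not name were compared between the groups by exact permutation tests, also after the data had been seen, from the mean signal of their spots raised to the floor, and entered no fit.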

Results

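MicroRNA (miRNA) levels were measured in liver grafts and in blood plasma of 8 male rats, 7 days after orthotopic liver transplantation. Lewis livers placed into BN recipients gave the acute rejection group, and BN livers placed into BN recipients gave the non-rejection group, so that donor strain and group went together. Each kind of sample was measured on 8 single-channel arrays for 350 miRNAs, 4 for acute rejection and 4 for non-rejection by the sample titles. The titles contradict each other for 2 animals. Animal 33 is titled non-rejection for its graft and acute rejection for its plasma, and animal 40 is titled the other way round. The remaining 6 animals, 3 per group, are called undisputed in what follows.

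The graft arrays detected between 126 and 182 miRNAs and the plasma arrays between 52 and 160. In the grafts, 153.5 ± 19.1 miRNAs were detected under acute rejection and 142.75 ± 17.5 under non-rejection (mean ± SD, n = 4 per group, two-sided exact permutation p = 0.514). In plasma the numbers were 140 ± 19.0 and 100.75 ± 39.4 (n = 4 per group, two-sided exact permutation p = 0.114). The 75th percentile of the probe signal, a measure of how far an array stood above background, ran from 7.15 to 35.8 intensity units on the graft arrays and from 1.02 to 13.2 on the plasma arrays. The plasma array of animal 38 had the lowest percentile and the fewest detected miRNAs. The scanner software marked 1 graft array (non-rejection array 4) and 6 plasma arrays (acute rejection arrays 1 to 4, non-rejection arrays 1 and 2) for evaluation, and the plasma array of animal 38 was not among them. All graft arrays shared 1 slide and 1 scan, and all plasma arrays another. On both slides animals 15, 16, 27 and 40 lay in row 2 and animals 33, 35, 37 and 38 in row 1, so slide row and group went together in all 8 grafts and in the plasma of the 6 undisputed animals. Some control probes whose targets the files do not name also differed between the groups. In the grafts the 4 probes named mr_1 were 1.47 to 1.49 log2 units higher under acute rejection before scaling (n = 4 per group, two-sided exact permutation p = 0.0286 for each) and 1.05 to 1.08 higher after it (exact p = 0.0571), and the 3 named hur_6 were 0.84 to 0.86 higher before scaling (exact p = 0.0286) and 0.43 to 0.45 after it (exact p from 0.2 to 0.257). In the undisputed plasma after scaling, the 4 named hur_2 were 4.06 to 4.08 higher, mr_1 2.61 to 2.90 and hur_6 2.53 to 2.96 (n = 3 per group, exact p = 0.1 for each, the smallest that 3 against 3 allows). The number of arrays limits the precision of every value given here.

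The first comparison asked which miRNAs differ between rejected and accepted liver grafts. miR-122, the dominant miRNA of hepatocytes, was 3.09-fold lower under acute rejection, at 13.33 ± 0.42 against 14.96 ± 0.17 (log2 scaled signal, mean ± SD, n = 4 per group). miR-192 and miR-194, which are transcribed together and are abundant in liver and gut, were 4.67-fold and 4.50-fold lower. miR-142-3p, a miRNA of blood cell lineages, was 6.60-fold higher, at 8.38 ± 0.15 against 5.66 ± 0.67 (n = 4 per group). miR-146b, which NF-kB signalling induces, was at least 8.20-fold higher, a lower bound because only 1 of the 4 non-rejection grafts detected it.

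**Figure D1:**
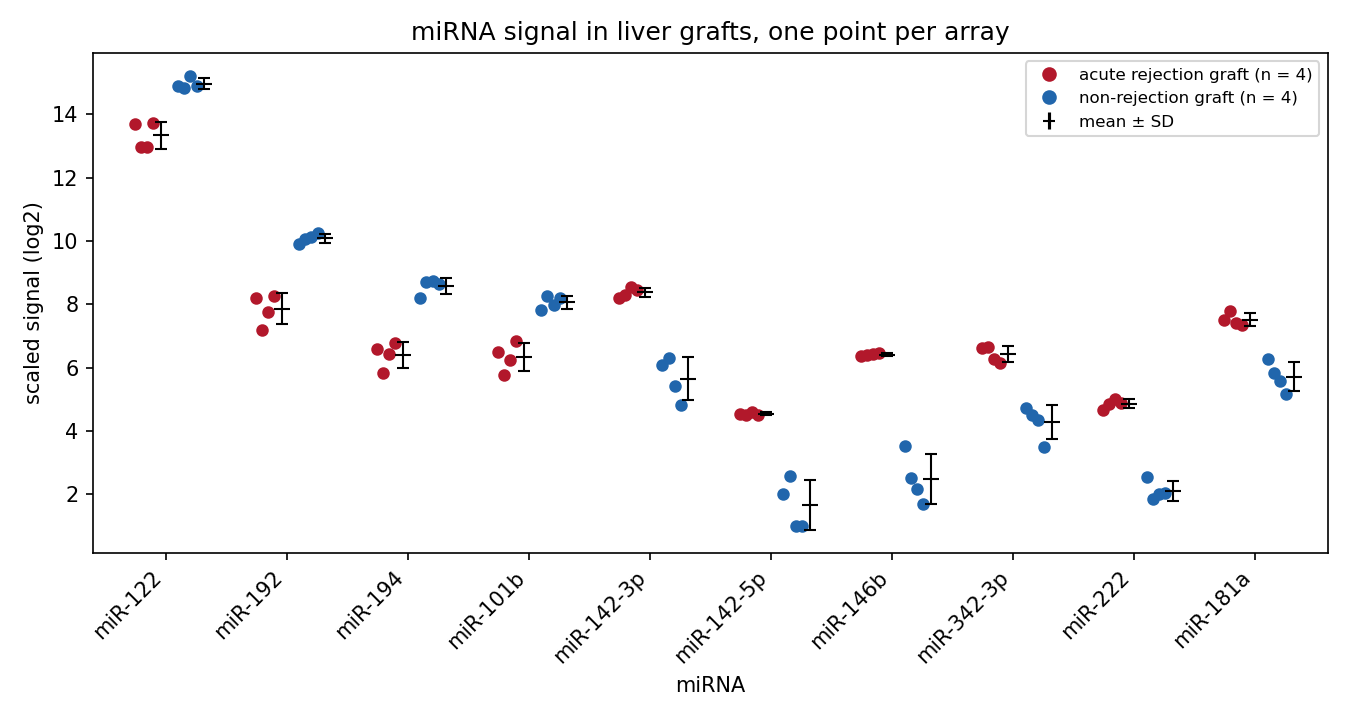
Scaled signal (log2) of 10 miRNAs in the liver grafts, with red points for the 4 acute rejection arrays, blue points for the 4 non-rejection arrays and black bars for the mean ± SD. The acute rejection points of miR-122, miR-192, miR-194 and miR-101b lie below all 4 non-rejection points, and those of the other 6 miRNAs lie above them.

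Of the hepatocyte list, 7 of 8 tested members fell and 0 rose, and adjusted over the list alone all 8 fell. Its median log2 change was −1.33, and the members included miR-122 (−1.63, SE 0.21), miR-101b (−1.73, SE 0.22), miR-193 (−1.04, SE 0.13) and miR-365 (−0.96, SE 0.15). miR-148b-3p changed by −0.34 (SE 0.14) and did not pass over all miRNAs. The list passed the camera set test (adjusted p = 0.00182), and had an adjusted p = 0.446 with an estimated correlation. The median of the list stayed below 0 by the percentile over all miRNA probes, after quantile normalization and without scaling. The fall of miR-122 itself did not pass after quantile normalization (log2 change −0.43, adjusted p = 0.165) or without scaling (log2 change −1.21, adjusted p = 0.143, both limma with Benjamini-Hochberg adjustment).

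All 7 tested members of the leukocyte list rose, and 7 also rose adjusted over the list alone. The median log2 change was 2.16. Besides miR-142-3p and miR-146b, these were miR-142-5p (detected on 1 non-rejection graft, at least 2.23-fold higher), miR-342-3p (2.16, SE 0.26), the granulocyte and monocyte miRNA miR-223 (1.82, SE 0.33), miR-146a (1.71, SE 0.31) and the lymphocyte miRNA miR-150 (1.12, SE 0.21). The list passed camera with an adjusted p = 0.00103, against an adjusted p = 0.446 with an estimated correlation. Of the inflammation-induced list, 5 of 6 tested members rose, over all miRNAs and adjusted over the list alone, with a median of 1.94. miR-222 was detected on no non-rejection graft and was at least 2.85-fold higher, its neighbour miR-221 rose by 2.18 (SE 0.22) and miR-21 by 0.83 (SE 0.17), while miR-212 stood at −0.18 (SE 0.15). This list shares miR-146a and miR-146b with the leukocyte list. Its camera result was an adjusted p = 0.00919, with an adjusted p = 0.446 with an estimated correlation. miR-155, which both lists name, has no probe on the array.

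Proliferation-linked miR-17-92 and its paralogs moved both ways. Among 8 tested members, 5 rose and 1 fell, and the counts were the same adjusted over the list alone. miR-17 rose by 1.23 (SE 0.11), miR-93 by 1.17 (SE 0.19) and miR-106b by 0.88 (SE 0.17), whereas miR-19b fell by 0.65 (SE 0.16). Of the red blood cell list, miR-16 (0.95, SE 0.16) and miR-15b (1.45, SE 0.30) rose, 2 of 4 tested. The erythroid miR-451 stood at 0.41 (SE 0.46, adjusted p = 0.475 by limma with Benjamini-Hochberg adjustment). Of the platelet list 4 of 7 rose and 2 fell, among them miR-223 and miR-103 (0.62, SE 0.16) upward and the endothelial miR-126 (−0.66, SE 0.18) and miR-26a (−0.93, SE 0.14) downward. The median log2 changes of these 3 lists were 0.58, 0.68 and 0.37, and camera gave an adjusted p = 0.203, 0.291 and 0.574.

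Of 8 tested members of the mesenchymal list, 5 fell and 0 rose. They included the smooth muscle miRNAs miR-145 (−0.85, SE 0.13) and miR-143 (−0.62, SE 0.14) together with miR-195 (−0.96, SE 0.12) and miR-10b, while miR-199a-3p stood at 0.25 (SE 0.31). miR-10b was detected on 1 acute rejection and 3 non-rejection grafts. It was 1.92-fold lower with undetected acute rejection values raised, which is no bound. miR-29a (−0.73, SE 0.11) and miR-29c (−0.98, SE 0.16), from a family known for targeting collagen transcripts, fell, and miR-29b (0.09, SE 0.13) did not pass. Of the epithelial list 2 of 5 fell, miR-31 (−1.55, SE 0.20) and miR-200a (−0.75, SE 0.26). In the miR-30 family 4 of 5 fell, miR-30c by 0.57 (SE 0.10) among them. In the let-7 family 4 of 8 fell, such as let-7a (−0.61, SE 0.14) and let-7c (−0.80, SE 0.15), and let-7i rose by 1.04 (SE 0.16). The let-7 median of −0.34 turned to 0.08 without scaling and to 0.08 after quantile normalization. The imprinted Dlk1-Dio3 cluster had 6 tested members, of which miR-487b fell by 0.71 (SE 0.17), and its median of −0.37 turned to 0.04 without scaling. None of these 6 lists passed camera, with adjusted p = 0.203 for the mesenchymal and miR-30 lists, 0.291 for the miR-29 and epithelial lists, and 0.412 for let-7 and the cluster. Their counts were the same adjusted over the list alone. Without scaling only 2 of all tested graft miRNAs passed as lower, so most of these falls and of the hepatocyte falls did not pass there.

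**Figure D2:**
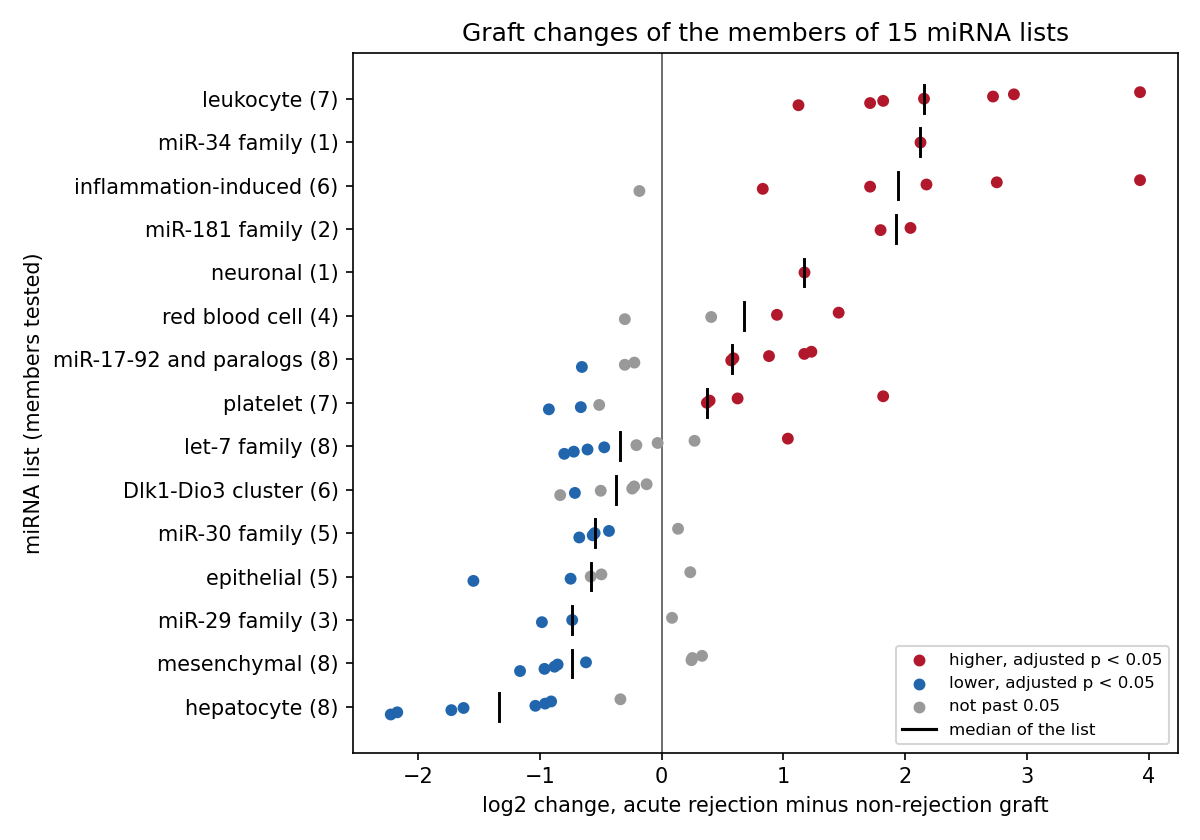
Log2 change between acute rejection and non-rejection grafts (4 arrays each, horizontal axis) of each tested member of 15 miRNA lists (vertical axis, number tested in brackets), red for higher and blue for lower at an adjusted p below 0.05, grey otherwise, with a black line at each list's median. The hepatocyte members lie to the left around a median of −1.33 and the leukocyte members to the right around 2.16, while the let-7 median of −0.34 turned to 0.08 without scaling and after quantile normalization and the Dlk1-Dio3 median of −0.37 to 0.04 without scaling.

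Lists with fewer than 3 tested members had no set test. Both tested miR-181 members rose, miR-181a by 1.80 (SE 0.23) and miR-181b by 2.04 (SE 0.25), and so did miR-34a, a p53 target, by 2.13 (SE 0.33) and miR-128, the only tested member of the neuronal list, which was detected on 1 non-rejection graft and was at least 1.63-fold higher. No member of the muscle list was tested. Outside the lists, miR-130b was detected on no non-rejection graft and was at least 1.68-fold higher, and it did not pass with undetected values raised to the lowest detected signal of their array (adjusted p = 0.0618, limma with Benjamini-Hochberg adjustment). miR-22 (−1.24, SE 0.15) and miR-99a (−1.22, SE 0.18) fell. miR-22*, the passenger strand of miR-22, was detected on 1 acute rejection graft and was at least 2.22-fold lower. miR-335 was detected on 1 acute rejection and 3 non-rejection grafts. It was 1.75-fold lower with undetected acute rejection values raised, which is no bound.

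In all, limma with Benjamini-Hochberg adjustment called 90 of 151 tested miRNAs at 0.05, with 42 higher and 48 lower. The 2 groups of 4 arrays did not overlap for 89 miRNAs, or 58.9% of those tested, where chance gives 2.86%. The 6 undisputed animals gave 88 calls, 84 of them among the 90. Without scaling 24 were called, 22 higher and 2 lower, and the median log2 change of all tested miRNAs moved from −0.18 to 0.23. With background correction by normexp 41 were called, 16 higher and 25 lower. Of the 90, 38 also changed by at least 2-fold, 27 higher and 11 lower, before undetected values were raised to the lowest detected signal. With the lower group's undetected values raised, several of them fell below 2-fold. These were miR-130b (1.68-fold), miR-128 (1.63), miR-674-5p (1.24), miR-324-5p (1.50), miR-532-5p (1.39), miR-21* (1.98), miR-335 (1.75) and miR-10b (1.92). With the graft labels of animals 33 and 40 exchanged, limma called 0, with 26 at an unadjusted p below 0.05.

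The second comparison asked whether rejection changes miRNAs circulating in plasma. Grouped by title, miR-122 was 2.60 log2 units apart between acute rejection and non-rejection plasma (SE 1.48, n = 4 per group) and miR-192 1.62 apart (SE 1.15), both with the higher mean under acute rejection. let-7d* differed by −2.10 (SE 0.73), miR-128 by −2.01 (SE 1.15), miR-451 by 1.53 (SE 0.85) and miR-21 by 0.72 (SE 0.69). None of these differences passed, and limma called 0 of 128 tested miRNAs, with 2 at an unadjusted p below 0.05 and 0.698 as the smallest adjusted p (Benjamini-Hochberg). No list passed camera, the smallest adjusted p being 0.164. The groups of 4 did not overlap for 3 miRNAs, or 2.34% of those tested, where chance gives 2.86%.

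In the plasma of the 6 undisputed animals, miR-122 was 32.9-fold higher under acute rejection, at 12.71 ± 0.33 against 7.67 ± 1.08 (log2 scaled signal, mean ± SD, n = 3 per group). miR-192 was 11.1-fold higher, at 10.04 ± 0.18 against 6.56 ± 0.97 (n = 3 per group). miR-21, abundant in liver and in many other tissues, was 3.58-fold higher. miR-128 was 13.3-fold lower and miR-223, carried by granulocytes and platelets, 4.00-fold lower. In all, limma with Benjamini-Hochberg adjustment called 27 of 128 miRNAs, 21 higher and 6 lower, with 46 at an unadjusted p below 0.05. The groups of 3 did not overlap for 55 miRNAs, or 43.0% of those tested, where chance gives 10%. With undetected values raised to the lowest detected signal of their array only 8 passed, 3 higher and 5 lower, among them miR-122, miR-192 and miR-21 upward and miR-128, miR-328 and let-7d* downward.

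**Figure D3:**
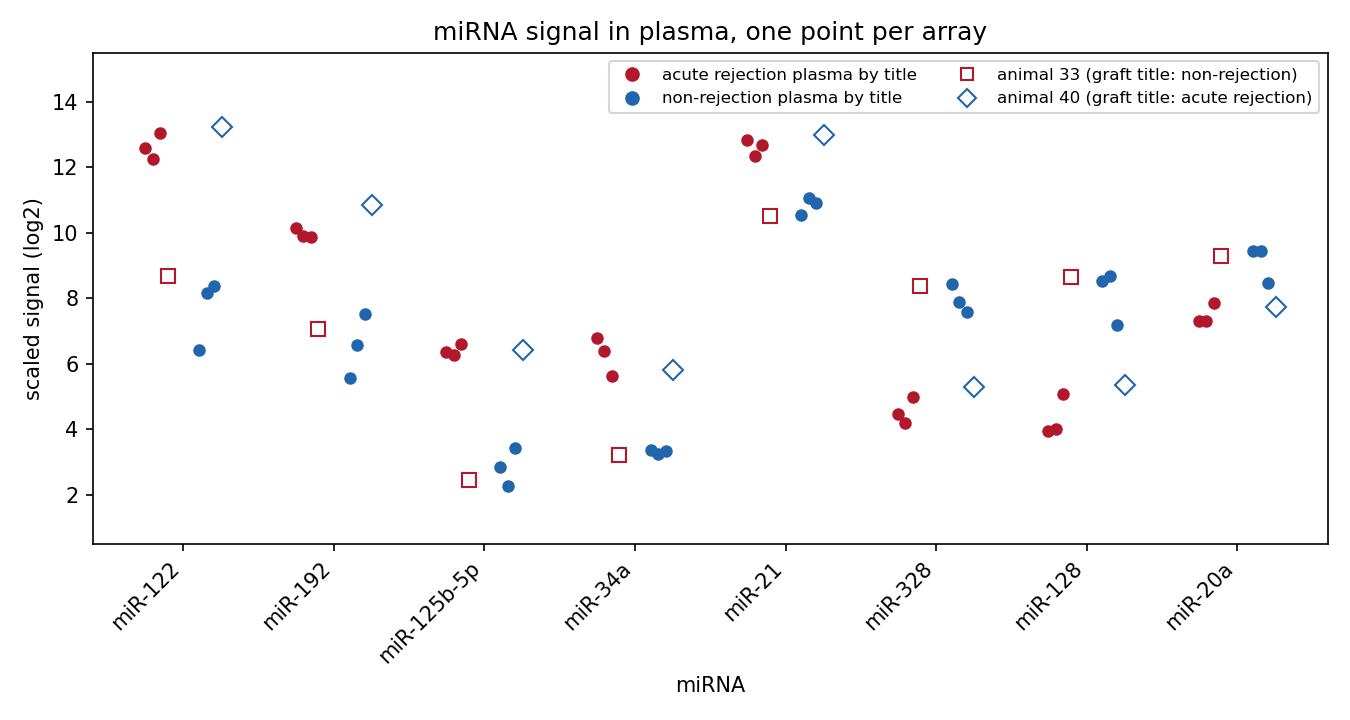
Scaled signal (log2) of 8 miRNAs in plasma, 1 point per array, coloured by plasma title (red acute rejection, blue non-rejection), with an open square for animal 33 and an open diamond for animal 40, whose graft titles name the other group. For miR-192 and miR-125b-5p the square, at 7.06 and 2.45, lies below the 3 filled red points of acute rejection.

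Of the hepatocyte list 4 of 7 tested members rose in the undisputed plasma and 0 fell, over all miRNAs and adjusted over the list alone. These were miR-122 (5.04, SE 0.57), miR-192 (3.48, SE 0.52), miR-193 (detected on 1 non-rejection array, at least 3.43-fold higher) and miR-101b (2.13, SE 0.36), and the list median was 2.13, above 0 also in the same 3 scalings as in the graft (camera adjusted p = 0.0599). In the inflammation-induced list 2 of 5 rose, miR-21 (1.84, SE 0.34) and miR-146a (1.80, SE 0.48), with a median of 1.80 (camera adjusted p = 0.167). The leukocyte list had 1 member higher, miR-146a, and 1 lower, miR-223 (−2.00, SE 0.45), of 7 tested. miR-142-3p stood at 0.13 (SE 0.67), miR-142-5p at −0.93 (SE 0.43) and miR-150 at 0.95 (SE 0.62). Of 10 tested members of miR-17-92 and its paralogs, miR-20a (−1.57, SE 0.41) and miR-17 (−1.54, SE 0.45) fell, or 4 adjusted over the list alone. Their median was −1.01, against 0.19 without scaling, where the median of all tested miRNAs stood at 1.31. That list passed camera (adjusted p = 0.0480) and had an adjusted p = 0.678 with an estimated correlation.

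The red blood cell list had 0 members called over all miRNAs and 2 adjusted over the list alone, 1 higher and 1 lower. miR-451 stood at 2.52 (SE 0.78, adjusted p = 0.0561 by limma with Benjamini-Hochberg adjustment) and miR-16 at 0.18 (SE 0.36). Of the platelet list 1 of 7 fell, miR-223, and miR-126 stood at 1.25 (SE 0.64). The leukocyte, red blood cell and platelet lists had medians of 0.13, 0.18 and 0.16 and a downward camera direction with adjusted p = 0.750, 0.847 and 0.421. By the percentile over all miRNA probes these medians turned to −0.25, −0.19 and −0.22, that of the red blood cell list also turned to −0.31 after quantile normalization, and the mean of the platelet list was −0.21. In the mesenchymal list 1 of 6 rose, miR-195 (1.49, SE 0.32), which stood at −0.14 with its undetected values raised as above, and in the miR-30 family 1 of 5, miR-30b-5p (1.30, SE 0.32). Each of these lists had 2 higher adjusted over the list alone. The 7 let-7 members, the 3 of the miR-29 family and the 4 of the Dlk1-Dio3 cluster had 0 calls over all miRNAs by limma or adjusted over the list alone. let-7a stood at −0.41 (SE 0.46), miR-29a at 0.69 (SE 0.41) and miR-494 at 1.99 (SE 0.67). Camera gave these 5 lists adjusted p between 0.175 and 0.750. Of lists with fewer than 3 tested members, miR-34a rose, detected on 1 non-rejection array and at least 3.72-fold higher, and in the neuronal list miR-138 was detected on no non-rejection array and was at least 1.88-fold higher while miR-128 fell by 3.73 (SE 0.54). miR-181a stood at 1.96 (SE 0.60), passing adjusted over the list alone only, and muscle miR-133b at −2.05 (SE 1.50). No epithelial member was tested.

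Other miRNAs that rose were miR-125b-5p (detected on 1 non-rejection array, at least 4.59-fold higher), miR-188 (3.24, SE 0.64), miR-874 (2.59, SE 0.45), miR-139-3p (2.46, SE 0.60) and miR-327 (2.45, SE 0.55). let-7d* fell by 3.02 (SE 0.36) and miR-328 by 3.36 (SE 0.38). Without scaling limma called 10 miRNAs in the undisputed plasma, all higher, and none of the 6 lower ones passed. Their log2 changes shrank to −2.53 for miR-128 (adjusted p = 0.283 by limma with Benjamini-Hochberg adjustment), −2.16 for miR-328, −1.82 for let-7d*, −0.80 for miR-223, −0.37 for miR-20a and −0.34 for miR-17. Without the weak array of animal 38 the calls rose to 73, 43 higher and 30 lower, with animals 35 and 37 alone as non-rejection.

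With the plasma labels of animals 33 and 40 exchanged, which gives each animal the group of its graft title, limma called 48 plasma miRNAs, 32 higher and 16 lower. These included 26 of the 27 from the undisputed animals, an overlap largely built in because 6 of the 8 arrays and their groups are the same, with miR-122 at 4.88, miR-192 at 3.51 and miR-128 at −3.67. In this grouping miR-451 passed at 2.17 and 5 of 10 members of miR-17-92 and its paralogs fell (camera adjusted p = 0.0202, with an adjusted p = 0.573 with an estimated correlation). Without non-rejection plasma array 3 (animal 38) the count of this grouping was 79. The exchanged grouping is also the split by slide row. The labelling spike-in controls of the plasma arrays differed by −0.36 log2 units between row 2 and row 1 (n = 4 per row, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows), and the hybridisation controls by −0.05 (exact p = 0.571). With slide row as a block the titles gave 0 calls by limma, with 1 at an unadjusted p below 0.05.

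The next question was whether rejection acted differently on graft and plasma, tested as the graft difference minus the plasma difference over all 16 arrays. By title, the difference was positive and passed for 5 of 7 tested members of the leukocyte list, 2 of 5 of the inflammation-induced list, 2 of 4 of the red blood cell list, 3 of 8 of miR-17-92 and its paralogs, 1 of 7 of the let-7 family and 1 of 7 of the platelet list. It passed for 0 of 7 hepatocyte members by limma, with 3 at an unadjusted p below 0.05 and a negative difference, and no set test was made for it. It was 3.55 for miR-142-3p (SE 0.73), 3.15 for miR-223 (SE 0.84) and 2.31 for miR-342-3p (SE 0.39). miR-142-5p, miR-146b and miR-130b also passed, each with its brightest probe detected on at most 1 non-rejection graft and on 3, 1 and 2 of 4 non-rejection plasma arrays, so that no lower bound can be given for them. Their values were 2.20, 2.42 and 1.55 with the undetected values of non-rejection grafts and acute rejection plasma raised to the lowest detected signal of their array. It was also positive for miR-27a (2.49, SE 0.46), let-7i (1.90, SE 0.47), miR-23a (1.88, SE 0.43), miR-15b (1.82, SE 0.44), miR-93 (1.41, SE 0.33) and miR-16 (1.12, SE 0.31). Of 108 tested miRNAs limma with Benjamini-Hochberg adjustment called 16 by title, all with a positive difference. The titles count each disputed animal as rejection in 1 tissue and as non-rejection in the other, which cannot both be true. In the undisputed animals alone 50 passed, 27 positive and 23 negative, the latter including the hepatocyte miRNAs miR-122 and miR-192. The single direction and the 0 hepatocyte calls therefore hold for the title grouping only. By title with animal as a random block, since graft and plasma came from the same animals, 27 passed, 22 positive and 5 negative, among them miR-122 (−4.70, adjusted p = 0.0326) and miR-192 (−4.15, adjusted p = 0.0164). Without the block miR-122 (−3.90, SE 1.63) and miR-192 (−3.52, SE 1.28) did not pass, and neither did miR-21 (0.44, SE 0.75), miR-146a (1.03, SE 0.71), miR-150 (0.95, SE 0.60), miR-126 (−0.71, SE 0.78), miR-451 (−0.79, SE 1.04) or let-7a (0.12, SE 0.38).

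In the 6 undisputed animals 50 differences passed, 27 positive and 23 negative, and the 16 were among them. There miR-122 stood at −6.45 and miR-192 at −5.53, both past the test, and miR-223 at 4.55. The count by title changed with single plasma arrays. All 16 stayed among 30 calls without acute rejection plasma array 4 (animal 33) and among 35 without non-rejection plasma array 4 (animal 40), while without non-rejection plasma array 3 (animal 38) there were 13, 6 positive and 7 negative, and 6 of the 16 stayed. The 16 also depended on the scaling, with 6 positive and 8 negative calls by the percentile over all miRNA probes, 6 and 11 by the median of detected probes, and 6 and 5 in the deposited value table. By title and without scaling limma called 0, with 25 at an unadjusted p below 0.05.

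Between graft and plasma of the same 6 undisputed animals, 19 of 108 shared miRNAs were called in both, 14 in opposite directions and 5 in the same direction. Chance with these counts gives 8.69 opposite and 8.17 in the same direction. Lower in graft and higher in plasma were 9 miRNAs, among them the hepatocyte miRNAs miR-122, miR-192, miR-193 and miR-101b and also miR-125b-5p. Higher in graft and lower in plasma were 5, namely miR-223, miR-128, miR-328, miR-17 and miR-20a. Higher in both were 5, namely miR-21, miR-146a, miR-34a, miR-210 and miR-674-3p, and 0 were lower in both. The plasma side of these counts rests on the 27 calls, where 8 passed with undetected values raised. Without scaling all plasma calls of these animals were higher, so none of the 5 lower in plasma passed there. Across miRNAs, which are not independent replicates, the graft and plasma changes had a Pearson correlation of −0.24 and a Spearman correlation of −0.22.

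**Figure D4:**
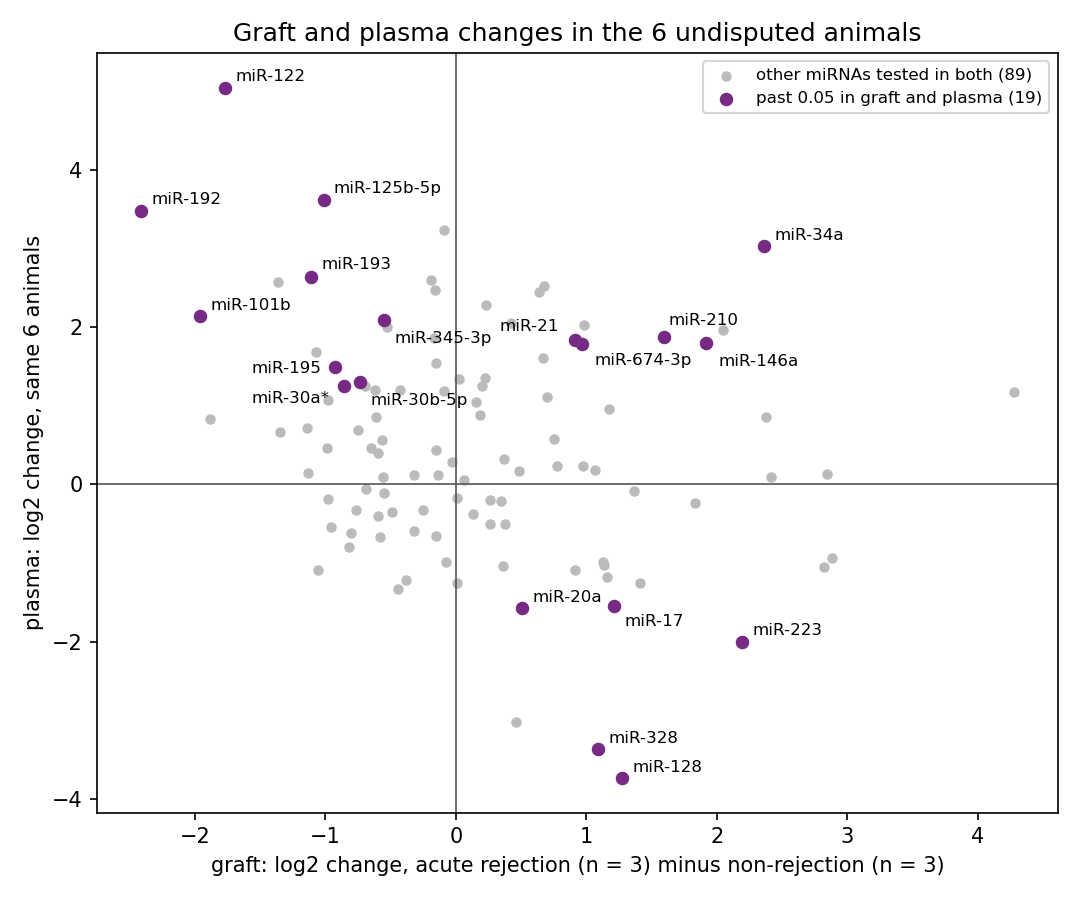
Log2 change between acute rejection and non-rejection in the graft (horizontal axis) and in plasma (vertical axis) of the 6 undisputed animals, 3 per group, for 108 miRNAs tested in both. The 19 miRNAs past the test in both are purple and named, with 9 at the upper left, 5 at the lower right and 5 at the upper right.

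The last comparison asked how the miRNAs of liver grafts differ from those of plasma. Relative to the shared scaling percentile, let-7a was 3.88 log2 units higher in graft (SE 0.19, n = 8 arrays each) and let-7f 3.89 higher (SE 0.24). miR-181a (4.17, SE 0.37), miR-125b-5p (4.16), miR-122 (3.75, SE 0.81) and the endothelial miR-126 (3.41, SE 0.39) were also higher in graft. Lower in graft than in plasma were the erythroid miR-451 (−3.91, SE 0.52), miR-223 (−3.29, SE 0.42), miR-128 (−2.86, SE 0.62), miR-19a (−2.83, SE 0.25) and miR-10b (−2.62, SE 0.38). The blood cell miRNAs miR-142-5p (−2.01, SE 0.26), miR-150 (−1.20, SE 0.30) and miR-16 (−0.81, SE 0.15) were lower in graft as well, and miR-21 (1.21, SE 0.38) and miR-146a (0.96, SE 0.35) were higher. miR-142-3p (0.74, SE 0.37) and miR-192 (0.50, SE 0.64) did not pass. Some of these sizes rest on signals near the floor or not above background and are uncertain. In the plasma fit, scaled signals ran from the floor of 2 to 29.5 for miR-181a and from 4.82 to 97.6 for miR-125b-5p. In the graft fit, the brightest probes of miR-142-5p and miR-128 were detected on 1 non-rejection graft. That of miR-10b was detected on 1 acute rejection and 3 non-rejection grafts.

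Of 108 tested miRNAs limma with Benjamini-Hochberg adjustment called 71 between graft and plasma, 42 higher and 29 lower in graft. The balance followed the scaling, with 29 higher and 44 lower by the percentile over all miRNA probes, 33 and 35 by total gene signals, 34 and 34 after quantile normalization, 17 and 18 with normexp, and 34 and 35 without non-rejection plasma array 3. Without scaling the split was 38 and 7, and the deposited values gave 66 and 16. Graft and plasma came from the same animals, and this fit took their arrays as independent, so its SEs and calls leave the pairing out. Tissue, slide and scan went together and cannot be told apart.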

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

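Of the tests given here, those on the weak array, red blood cell RNA, scaling, the share of hepatocytes, donor strain, slide row and the arrays of an animal kept together were chosen after the results had been seen. An array far from the other 3 of its group was found in 16 of 124 groups of 4 values checked. Chance gives about 5% for values picked without regard to the groups. Animal 33 accounts for 8 of the 16 and animal 40 for 4. Some plasma miRNAs checked were named for large differences among the undisputed animals. That choice favours values where animals 33 and 40 lie apart from their titled groups. The 5% does not hold there, and these counts are no independent evidence on the titles.

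The plasma of animal 33, titled acute rejection, stood apart from the other acute rejection plasma in let-7d* (7.58 log2 units), miR-19a (7.19), miR-192 (7.06), miR-125b-5p (2.45), miR-193 (3.11) and miR-327 (6.13). The plasma of animal 40, titled non-rejection, stood apart in miR-34a (5.82) and miR-138 (5.49). On a plasma scale set by the undisputed animals, from 0 at the non-rejection mean to 1 at the acute rejection mean, animal 33 minus animal 40 was −0.932 (SD of a difference within a group 0.324), consistent with plasma titles that were exchanged. On the same scale for the graft animal 40 minus animal 33 was 0.690 (SD 0.179), which argues against exchanged graft titles. The graft and plasma titles of an animal cannot both be correct if its number is, since each animal received 1 kind of graft. On the plasma scale the undisputed non-rejection animals did not lie together, with animals 35 and 37 at 0.0063 and 0.0120 and animal 38 at 0.562. Animals 33 and 40 lay at 0.028 and 0.960. Both scales also follow slide row. Values set by row therefore remain open, with correct plasma titles and wrong graft titles or animal numbers. These data do not decide between the accounts.

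By title the plasma arrays gave 0 calls (limma, 2 at an unadjusted p below 0.05), which each of the 35 splits of the 8 arrays reaches by construction, so the count of splits says nothing about chance. The highest other split gave 48 calls, which points to a structure of the samples, and it is the split that follows both the graft titles and the slide rows. In the 6 undisputed animals 27 miRNAs were called and the highest other split gave 0, but 10 splits are too few for a share under 0.05.

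For the plasma differences among the undisputed animals, miR-122 and miR-192 among them, no biological cause was tested. The sizes of the called changes did not rest on the weak array of animal 38. Without it they were 1.06 times those with it (median over the called miRNAs, 25th percentile 0.917). These miRNAs were called with that array included, so the ratio cannot show how far the array shaped which miRNAs passed. Whether red blood cell RNA was the whole cause of the plasma differences could not be decided. miR-451 exceeded the nearer of miR-16 and miR-92a by 2.33 (SE 0.861), where red blood cells carry all of them. In undisputed non-rejection plasma, animal 38 last, scaled signals were 954.7, 959.6 and 1213 for miR-16 and 2180, 1249 and 1508 for miR-92a. Those of miR-451 were 562.1, 477.5 and 3671, above both only in animal 38. Where miR-16 and miR-92a already stood higher, added red blood cell RNA could raise them less than miR-451, so the gap cannot exclude it. Slide row and group parted in 0 of the 6 undisputed animals, so a row effect and rejection cannot be told apart in them.

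For the lower hepatocyte and higher leukocyte miRNAs in the rejected grafts no change in the cells present was measured, and miR-142-3p, miR-146a, miR-150 and miR-223 were detected in all 4 non-rejection grafts too. Scaling alone did not set the direction of the hepatocyte changes, since without scaling their 75th percentile was −0.530 (median −0.917). Most of the hepatocyte falls did not pass without scaling, so whether they pass depends on it. The leukocyte changes were not part of this test. A lower share of hepatocytes alone would raise the mesenchymal list like the leukocyte list if its members came only from mesenchymal cells. The mesenchymal list did not rise so, with a 75th percentile of 0.248 against a 25th percentile of 1.77 for the leukocyte changes. The lists do not name the cells present, so these values cannot exclude that cause. Donor strain and group parted in 0 of the 8 grafts, and slide row followed the group as well, so neither can be told apart from rejection. Other splits of the 8 arrays gave at most 0 calls against 90 for the real split. That is 1 of 35 splits, the smallest share that 4 against 4 allows, which argues against chance without excluding it. The 6 undisputed animals gave 88 against 0, with 10 splits too few for a share under 0.05.

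Acute rejection graft array 4 (animal 40) detected 182 miRNAs against 142 to 145 on the others, with a 75th percentile of 35.8 against 10.8 to 14.8. Non-rejection graft array 1 (animal 33) stood apart in miR-223 (7.92) and miR-194 (8.19). Non-rejection graft array 4 stood apart in miR-150 (5.15), and array 2 in miR-451 (7.67). In plasma, acute rejection array 3 stood apart in miR-16 (10.66), and non-rejection array 3 (animal 38) in miR-181a, which lay at the floor of 1 log2 unit.

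Graft and plasma effects of rejection differed by an interaction term of limma for miR-142-5p (3.85), miR-130b (3.46), miR-342-3p (2.31), miR-27a (2.49), miR-142-3p (3.55), miR-146b (3.34), miR-23a (1.88), miR-93 (1.41), miR-15b (1.82), let-7i (1.90), miR-223 (3.15) and miR-16 (1.12). The sizes for miR-142-5p, miR-130b and miR-146b rest on values not above background, and with those of non-rejection grafts and acute rejection plasma raised to the lowest detected signal they were 2.20, 1.55 and 2.42, which are no bounds, since non-rejection plasma was undetected on some arrays too. Of 100 draws of the labels 4 gave at least the 16 calls of the real labels (highest other 52), but they did not keep the arrays of an animal together. Of all 1120 arrangements that did, 58 gave at least the 16 calls (highest other 48), above 5 in 100. With animal as a random block 54 gave at least the 27 calls (highest other 57), just under 5 in 100. Both variants were chosen after the results had been seen and fall close to the limit on either side. Chance therefore stays open for the 16 and for the 27, both of which rest on the contradictory titles. For graft against plasma, 1 of 100 draws gave the 71 calls (highest other 29). Of 256 exchanges of tissue labels within animals 2 did, the real labels and their mirror image (highest other 69). Both shares are the smallest that these draws and exchanges allow, and they argue against chance without excluding it.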

How the results depend on the processing

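The alternatives with label settings joined to another choice, slide row, normexp, undetected values raised to the lowest detected signal, the graft fit without the array marked for evaluation and the fit without animal 38 were chosen after the data had been seen, the others before. Where a count moved, the cause was not tested, except that leaving out arrays or miRNAs lowers the number compared. The graft calls, 90 by title, stood at 24 without scaling, 41 with normexp and 38 with a spread shared over all arrays. They stood at 38 at 2-fold or more, before undetected values were raised. With the graft labels exchanged they were 0 (limma, 26 at an unadjusted p below 0.05), and leaving out each array they lay between 83 and 92. With a replicate block they were 79 in the graft and 0 in plasma. The replicate numbers do not pair the arrays, since correlations within a number ran from −0.56 to −0.21 in the graft and were −0.50, −0.58, 0.37 and −0.87 in plasma, none of them the best for its array.

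The 0 plasma calls by title ranged from 0 to 1 leaving out each array. The 27 calls without animals 33 and 40 became 73 without animal 38 as well, 22 by the percentile over all miRNA probes, 27 by the median of detected probes, 25 after quantile normalization, 10 without scaling and 8 with undetected values raised to the lowest detected signal. The 48 with exchanged plasma labels became 49, 54, 42 and 6 under these scalings. Leaving out acute rejection plasma arrays 1 to 4 gave 38, 37, 43 and 33, and non-rejection arrays 1 to 4 gave 37, 41, 79 and 43.

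For the difference between the tissues' effects, 16 by title, quantile normalization gave 8, no scaling 0 (limma, 25 at an unadjusted p below 0.05), normexp 5, total gene signals 5, no filter 38 and detection on every array 8. Leaving out each array gave from 13 to 35. Leaving out animals 33 and 40 gave 50, exchanged plasma labels 58, exchanged graft labels 0 (limma, 12 at an unadjusted p below 0.05) and animal as a random replicate block 27. The sign turned for miR-16 without scaling (−0.29) and for miR-21 with exchanged plasma labels (−0.87). Graft against plasma, 71 by title, gave 45 without scaling, 35 with normexp, 157 with no filter and 29 with detection on every array, and from 69 to 83 leaving out each array.

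Over all named miRNAs and alternatives, 2856 results kept their direction and side of the threshold, 384 became stronger, 160 weaker and 2 reversed, and 84 that passed neither time changed sign. In plasma 50 miRNAs were detected on all 8 arrays, against 116 in the graft. A miRNA not detected is not shown to be absent. Slide as a block within a tissue was not run, since all arrays of a tissue share 1 slide.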

Other observations

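No test of an explanation was made for the values given here, which were chosen after they had been seen. Of 350 miRNAs, 152 were detected on at least 4 graft arrays, 130 on at least 4 plasma arrays and 111 on both, while 141 were detected on none of the 16 arrays. On at least 4 graft arrays and no plasma array were 16 miRNAs, among them let-7e, miR-99b, miR-200c, the fibroblast miRNA miR-199a-5p and the smooth muscle miRNA miR-145, which fell under rejection in the graft (−0.85, SE 0.13). The passenger strand miR-21* was also among them and rose in the graft by 1.07 (SE 0.23), in the direction of miR-21 itself. On at least 4 plasma arrays and no graft array were 7, namely the erythroid miR-144 (7 of 8 arrays), miR-215, which shares its seed with miR-192 (7 of 8), miR-300-5p (8 of 8), miR-184, miR-138, miR-133b and miR-7a*.

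With the plasma labels of animals 33 and 40 exchanged, 28 of the 108 shared miRNAs were called in graft and plasma, 23 in opposite directions and 5 in the same direction. Lower in graft and higher in plasma were 13, to which miR-101a, miR-30a, miR-497 and miR-99a belonged besides miR-122 and miR-192. Higher in graft and lower in plasma were 10, among them miR-130b, miR-27a, miR-23a, let-7i and miR-425. This grouping carries the same doubt about slide row as the plasma differences themselves.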
